A study of Homo sapiens with 4 samples.

How the data were processed

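Gene expression was measured by RNA sequencing in 4 libraries, 2 labelled control and 2 labelled creatine, all labelled as DLD-1 cells of wild-type genotype. Libraries were made from total RNA with a TruSeq RNA kit, per the labels' protocols, which do not say whether the kit kept strand. The submitters' processing notes name FastQC 0.11.9, HISAT2 2.2.1, featureCounts and DESeq2 with the GRCh38 genome. The gene annotation release, the strand setting and the treatment of reads that match several places are not given in the sources used here. Reads from overlapping or antisense genes, and from near-identical copies such as pseudogenes, may for that reason have been assigned to a neighbour or dropped.

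The deposited table held whole-number counts of reads per gene symbol, not normalized, as made by the authors, together with a gene length in bases. It had 34545 symbols, of which 34408 matched GENCODE 29 on GRCh38, which gave coordinates, gene types and the GC content of transcripts. Of the 19931 protein-coding symbols of GENCODE 29, 1326 were not analysed here, nor were the transcripts of the mitochondrial genome. Total counts were 59860043 and 49207427 in control libraries 1 and 2, and 51073738 and 48249693 in creatine libraries 1 and 2. A floor of 3 counts, the level that a count of 0 still allows, came to 0.0501, 0.0610, 0.0587 and 0.0622 CPM in the same order. Floors and counting errors cover counting only, since the reads carry no molecular identifiers.

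Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 15302, and libraries were scaled with TMM factors between 0.993 and 1.01. A quasi-likelihood model with the group as its only term was fitted, and p-values were adjusted by Benjamini-Hochberg over all genes kept, with a threshold of 0.05. Adjusted p-values of single genes below are from this test unless another tool is named. The model has 2 residual degrees of freedom per gene and borrows spread across genes, for a median of 22.9 in total. CPM values are given as the mean ± SD of the 2 libraries of a group, scaled by the same factors. Log2 fold changes are creatine over control, with their standard error.

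Gene lists, 40 in number, were fixed before the data were examined, as were the tests, the repeated fits called planned in the closing section and the rule for the genes to be named. Of these lists, 2 had no measured member and are not analysed here, and some were measured in part, among them the ATF4 list (31 of 41 members) and oxidative phosphorylation (61 of 76). The other 38 were tested with camera from limma 3.58.1, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Each was tested again with an estimated correlation and with fry. These last 2 tests rest on the 2 residual degrees of freedom, so few lists could pass them. Not passing them is weak evidence against a shift. The rule named 17 fixed genes, the 8 highest and 8 lowest log2 fold changes past the threshold, the 4 smallest adjusted p per direction and up to 4 genes per list with the smallest adjusted p. For the highest and lowest changes, a mean of at least 5 CPM in the higher group was required, with both creatine libraries on the same side of both controls. Some genes that the rule named are not reported here. Genes named outside this rule are said to be chosen after their values were seen.

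The procedure was tested on simulated counts drawn from the means and library sizes of this comparison, with 14950 genes passing the filter. Of 50 genes changed at each size, 28% were recovered at 1.25-fold, 88% at 1.5-fold, 96% at 2-fold and 96% at 4-fold, with 9 false calls. Changed genes were drawn only from those above a minimum average level, and every gene was given the spread typical of its level. The recovery rates therefore do not cover genes of low count or of wider spread. In simulated libraries with no changed gene but with the GC and length trends measured here, the test made 1800 calls, and 0 once the trends were removed.

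The fit was repeated, as set out beforehand, with other scalings, no filter or a stricter filter of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, edgeR with robust estimation, a replicate block, and each library left out. Alternatives chosen after seeing the data were a correction for GC content and gene length, a correction for GC content alone, and thinning every library to the smallest total. The corrections fitted a smooth trend of each library's log2 CPM on transcript GC, with or without log2 gene length (mgcv 1.9.3), and entered it as an offset in the same edgeR model. They remove any change that follows GC content or length, whatever produced it. Values "after correction" below are from the fit with GC content and length. Of the genes tested, 23 had no GC value and were given the median.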

Results

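Cells labelled as DLD-1, a line derived from a colorectal carcinoma, were profiled by RNA sequencing after treatment with creatine or without it, with 2 libraries in each of the 2 groups. Creatine stores high-energy phosphate and enters cells through the transporter SLC6A8. The study addressed its role in ferroptosis, a death driven by iron and lipid peroxidation, with attention to ERK signalling and the ferroptosis suppressor FSP1 (AIFM2). Dose and duration are not given in the labels. Total counts per library lay between 48249693 and 59860043. Libraries of the same group differed by more than sampling noise, with a chi-square per degree of freedom of 15.4 for the controls and 8.62 for the creatine pair, against 33.3 to 52.0 between groups. The first principal component of log2 CPM, with 39.1% of the variance, separated the groups, and the second, with 31.2%, separated the libraries within each group. The labels do not say whether libraries came from separate cultures, so p-values measure the spread between these libraries, which may be technical. An exact permutation test of 2 against 2 cannot go below p = 0.333 (two-sided), so the gene tests rest on the spread that edgeR pools across genes.

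Transcripts of colon epithelium were at or near the detection floor in all 4 libraries, while mesenchymal transcripts were abundant. EPCAM, an adhesion gene of epithelial cells, had 2 counts in control 1 and 0 in the other 3 libraries, which is under the floor of 3 counts. CDX2, which specifies intestinal epithelium, had 8 counts in control 1 and 0 elsewhere, and VIL1, the brush border villin, had 7 and 0. CDH1 (E-cadherin) reached 0.301 ± 0.0225 CPM in controls and 0.299 ± 0.127 CPM with creatine (SD, n = 2 each), from 10 to 20 counts per library. Of 29 enterocyte and goblet cell genes, 27 were under 1 CPM in every library, as were 12 of 26 epithelial junction genes. A mean over 10 CPM was reached by 1 of the 29 and by 6 of the 26. Of 26 mesenchymal and TGF-beta genes, 22 had a mean over 10 CPM. The intermediate filament vimentin (VIM) stood at 2613 ± 105 CPM in controls and 2346 ± 23.7 CPM with creatine and ranked 18 among all symbols, and MMP14, a membrane metalloprotease, ranked 29. N-cadherin (CDH2) was at 169 and 186 CPM. The keratins KRT8 and KRT18, at 193 and 200 CPM in controls, were among the most abundant of the epithelial list. Of 10 fibroblast genes 0 had a mean over 10 CPM, of 15 immune genes 1 (CSF1R, 16.4 CPM in controls), and of 9 endothelial genes 1, the receptor TIE1 at 376 CPM in controls. With creatine, TIE1 and the brush border peptidase ANPEP were lower (-0.27 and -0.36), but not after the correction for GC content described below (-0.00 and -0.13), and TIE1 did not pass without creatine replicate 1 (adjusted p = 0.0715). The mesenchymal list had 3 of 25 tested members higher and 6 lower, or 7 lower adjusted over the list alone (camera adjusted p = 0.053, median -0.16). That list passed with no low-count filter (camera adjusted p = 0.022) and not after the correction (0.57, median -0.02). With 1 library left out its median lay between -0.17 and -0.11. The epithelial junction list had 1 higher and 2 lower of 19, adjusted over the list alone as well (camera adjusted p = 0.80). The lists were fixed beforehand, and the genes singled out from them here were chosen after their values were seen. DLD-1 is described as an epithelial line, so the libraries are called below by their labels.

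**Figure D1:**
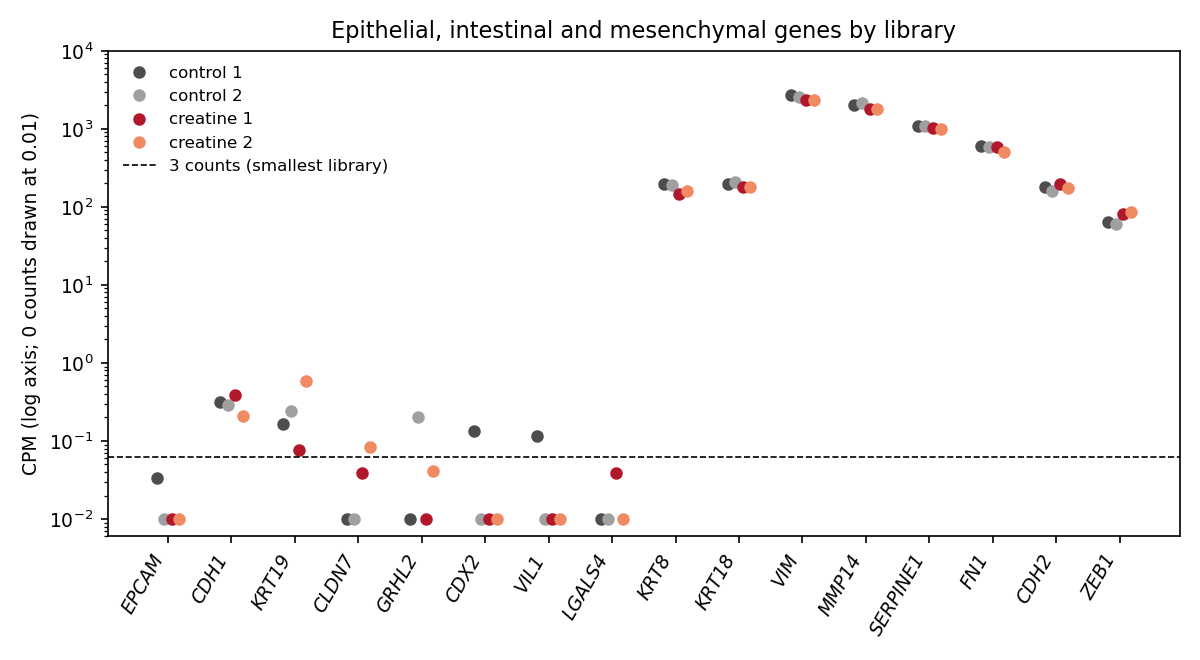
Normalised counts (CPM, log axis) of epithelial, intestinal and mesenchymal genes in each of the 4 libraries, with 0 counts drawn at 0.01 and a dashed line at 3 counts of the smallest library. EPCAM lies under that line in every library, while VIM has means of 2613 CPM in controls and 2346 CPM with creatine.

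Creatine-treated and control libraries differed in 3001 of 15302 genes tested, 1400 higher and 1601 lower with creatine, mostly by small amounts, since 41 of them changed by 2-fold or more. That count was 4 with DESeq2, 67 with no low-count filter, 66 without control replicate 1, 89 without control replicate 2, and 8 and 2 after the 2 corrections for GC content described below. The gene with the smallest p was BCAR1, the docking protein p130Cas of focal adhesions (chromosome 16, 75228187 to 75268053, GRCh38), which fell from 53.7 ± 2.56 to 24.7 ± 1.62 CPM (SD, n = 2 each), a log2 change of -1.12 (SE 0.10, adjusted p = 6.8e-07). MRPL23, a protein of the mitochondrial ribosome (chromosome 11, 1947278 to 1984522), fell from 25.6 ± 7.90 to 8.80 ± 1.56 CPM, a log2 change of -1.54 (SE 0.17, adjusted p = 2.9e-05). The transcriptional repressor CIC and the RNA-binding protein gene RAVER1 fell by 0.67 and 0.64 on the log2 scale, and the lowest genes also held SHROOM2 (-1.13), KCNC4 (-1.01), SH3RF3-AS1 (-0.89), TRIM62 (-0.88) and ZIC2 (-0.84). Genes that rose with the smallest p were the noncoding RNA ZFAS1, the ribosome maturation factor RSL24D1, the ribosomal protein gene RPS9 and NAMPT, the rate-limiting enzyme of NAD salvage, by 0.60, 0.52, 0.86 and 0.48. The highest changes included ZMAT1 (0.88), ASAH2 (0.86), ZNF221 (0.82), CALCB (0.78), SMIM8 (0.76) and FRA10AC1 (0.75). SMN2 had the highest value, 1.76 (adjusted p = 0.0016), and did not pass with DESeq2 (adjusted p = 0.162) or with robust edgeR (adjusted p = 0.364). It shares nearly all of its sequence with SMN1, so the level of SMN2 alone is uncertain. RPS9 lies over other annotated genes, differed between the controls (482 and 315 CPM), and did not pass with robust edgeR (adjusted p = 0.216). Without creatine replicate 1, the count of changed genes was 1162 and ZMAT1, ASAH2, SMIM8 and SH3RF3-AS1 did not pass (adjusted p = 0.121, 0.140, 0.0920 and 0.0525). Without creatine replicate 2, the count was 1949 and CALCB and TRIM62 did not pass (0.0802 and 0.0876), and SMIM8 did not pass without control replicate 1 (0.0558).

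The direction of change followed the GC content of the transcripts. Among genes with GC under 45%, 1179 of 5200 rose and 12 fell, and among genes with GC over 55%, 28 of 4505 rose and 1239 fell. Spearman's rho between log2 fold change and GC was -0.534 across 15279 genes, which are not independent replicates. Each control library lay on one side and each creatine library on the other, with slopes of 0.09 and 0.13 in controls and -0.13 and -0.08 with creatine, in log2 CPM per 10 points of GC. After correction for GC content and gene length, 379 genes passed, 208 higher and 171 lower, of which 249 had also passed before, 248 of them in the same direction. BCAR1 (-0.78), MRPL23 (-1.29), CIC (-0.32), RAVER1 (-0.33), ZFAS1 (0.63), RSL24D1 (0.23), RPS9 (1.08) and NAMPT (0.28) passed in the corrected fit. Of the highest and lowest changes above, KCNC4, TRIM62, ZIC2, ZMAT1, ASAH2, SMIM8 and FRA10AC1 did not (adjusted p = 0.0706, 0.145, 0.121, 0.134, 0.0875, 0.142 and 0.0706). Because the trend separates the groups, values after this correction are given below as well.

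**Figure D2:**
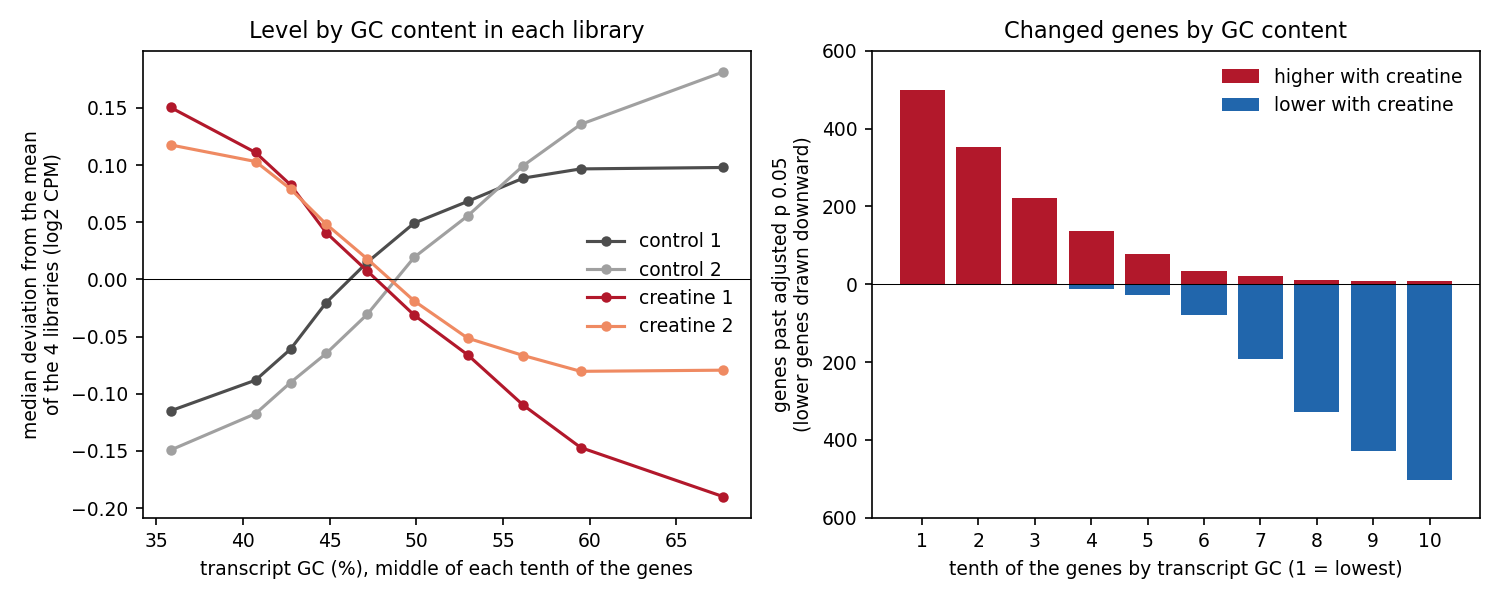
Left, the median deviation of each library from the mean of the 4 libraries (log2 CPM) in 10 equal groups of genes ordered by transcript GC, where controls lie lowest in the GC-poor groups and highest in the GC-rich groups. Right, the number of genes past adjusted p 0.05 in each group, higher with creatine drawn upward and lower drawn downward, from 498 higher and 0 lower in the group of lowest GC to 8 higher and 503 lower in the highest.

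Genes of ferroptosis moved both ways with creatine, and no shift of either of its gene lists as a whole was detected. SLC7A11, the cystine importer that feeds glutathione synthesis (chromosome 4, 138164097 to 138242349), rose from 121 ± 4.08 to 171 ± 9.94 CPM, a log2 change of 0.50 (SE 0.07, adjusted p = 1.5e-04). The lipid peroxidase GPX4 was at 91.9 ± 10.4 and 85.7 ± 0.264 CPM (log2 change -0.10, adjusted p = 0.44). AIFM2, which encodes FSP1 (chromosome 10, 70098223 to 70132934), was at 14.5 ± 1.31 and 13.1 ± 0.171 CPM, a log2 change of -0.14 (95% interval -0.42 to 0.13, adjusted p = 0.51). Among 31 suppressors tested, 5 were higher, 1 was lower and 25 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.32). ACSL3 and CISD2 were higher (0.28 and 0.42), and glutathione reductase GSR was lower (-0.37, adjusted p = 0.004). Among 30 promoters, 8 were higher, 4 were lower and 18 did not pass, again the same adjusted over the list alone (camera adjusted p = 0.48). The spermidine acetyltransferase SAT1 (0.46) and the autophagosome protein gene MAP1LC3B (0.37) rose, while STEAP3 (-0.36), an iron reductase, and CHAC1 (-0.36), which degrades glutathione, fell. ACSL4, which loads membranes with polyunsaturated lipid, and the transferrin receptor TFRC were also higher (0.29 and 0.19). FTH1 and NCOA4, of iron storage and its release, were at 0.06 and 0.07 (adjusted p = 0.54 and 0.50). After correction SAT1 (0.28, adjusted p = 0.015), MAP1LC3B (0.45, 1.6e-04) and GSR (-0.35, 0.015) passed. Corrected values of SLC7A11 (0.20, adjusted p = 0.073), ACSL3 (0.09), CISD2 (0.10), ACSL4 (0.05), TFRC (0.03), STEAP3 (-0.14) and CHAC1 (-0.18) did not pass. GPX4 and AIFM2 took the opposite sign after correction (0.09 and 0.04) and did not pass (adjusted p = 0.56 and 0.94). The counts of changed members were then 2 for suppressors and 2 for promoters. Without creatine replicate 1, 1 suppressor and 7 promoters passed, and ACSL3, CISD2, GSR, ACSL4 and TFRC did not (adjusted p = 0.0766, 0.101, 0.0516, 0.174 and 0.0958). Without creatine replicate 2, 3 suppressors and 7 promoters passed, and CISD2 (0.0566) and TFRC (0.288) did not, and CISD2 did not pass without control replicate 1 (0.146).

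Of the genes that carry creatine into the cell or handle it, the transporter SLC6A8 (chromosome X, 153688099 to 153696593) fell from 142 ± 4.03 to 121 ± 3.84 CPM, a log2 change of -0.24 (SE 0.07, adjusted p = 0.019). SLC16A12, a monocarboxylate carrier that also moves creatine, rose from 13.9 ± 0.917 to 19.8 ± 2.85 CPM (0.51, adjusted p = 0.008). The synthesis enzyme GAMT (-0.22, adjusted p = 0.14) and the brain-type creatine kinase CKB (-0.23, adjusted p = 0.51) did not pass, and GATM was at 0.206 and 0.322 CPM. The list of 6 tested genes had 1 higher and 1 lower, adjusted over the list alone too (camera adjusted p = 0.78), and its median of -0.22 and mean of 0.03 differ in sign. After correction its camera adjusted p was 0.57. SLC6A8 has a GC content of 61.3%, and its corrected change was 0.04 (adjusted p = 0.79), of opposite sign. SLC16A12 was at 0.36 after correction (adjusted p = 0.14). Without creatine replicate 1 neither gene passed (adjusted p = 0.204 for SLC6A8 and 0.179 for SLC16A12), and SLC6A8 did not without creatine replicate 2 (0.0598).

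Of 24 tested transcripts that respond to ERK signalling, 7 were lower with creatine, among them the immediate early transcription factor EGR1 (chromosome 5, 138465490 to 138469315), which fell from 22.6 ± 1.10 to 12.8 ± 0.455 CPM, a log2 change of -0.82 (SE 0.12, adjusted p = 2.1e-04). The ERK phosphatase gene DUSP4 fell from 104 ± 1.61 to 77.9 ± 6.27 CPM (-0.42, adjusted p = 0.001), and FOSL1 (-0.29), MYC (-0.27) and ETV4 (-0.29), 3 transcription factors of the list, fell as well. SPRY4, a feedback inhibitor, was at -0.05 (adjusted p = 0.68), and DUSP6 was at 0.393 and 0.540 CPM. Of the list, 0 were higher and 17 did not pass, or 12 lower and 1 higher adjusted over the list alone. The list passed camera as lower with the preset correlation (adjusted p = 0.0093, median log2 change -0.15) and not with an estimated correlation (0.70). The kinase gene MAPK3 was at -0.10 (adjusted p = 0.57). Of 25 genes of the RAS-ERK cascade, 3 were higher, among them RPS6KA3 (0.38) and NRAS (0.31), which did not pass after correction (0.18 and 0.04), and 7 were lower, or 8 lower adjusted over the list alone (camera adjusted p = 0.59, and 0.85 after correction). After correction EGR1 (-0.68, adjusted p = 0.0035) and DUSP4 (-0.26, 0.04) passed, with SPRY2 (-0.31, 0.041), named after its value was seen. FOSL1 (-0.16), MYC (-0.11) and ETV4 (-0.06) did not, nor did the list (camera adjusted p = 0.57, median -0.01). Without creatine replicate 1, 2 members passed, and FOSL1, MYC and ETV4 did not (adjusted p = 0.0581, 0.138 and 0.401). Without control replicate 1 the list (camera adjusted p = 0.0909) and ETV4 (0.0594) did not pass, and without control replicate 2 the count was 11.

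**Figure D3:**
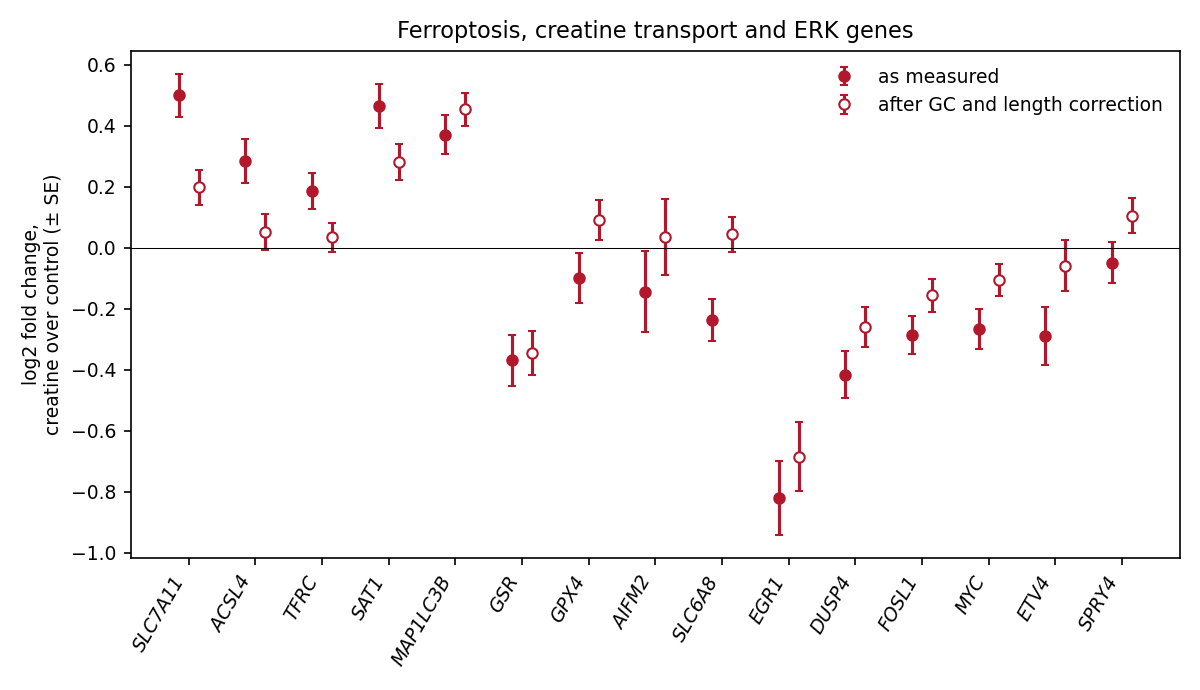
Log2 fold change, creatine over control, with its standard error, for 15 genes of ferroptosis, creatine transport and ERK signalling, as measured (filled) and after GC and length correction (open). SLC6A8 moves from -0.24 to 0.04 and SLC7A11 from 0.50 to 0.20, while EGR1 moves from -0.82 to -0.68 and MAP1LC3B from 0.37 to 0.45.

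Of 75 cytosolic ribosomal protein genes, 48 were higher, 0 were lower and 27 did not pass, or 56 higher adjusted over the list alone, with a median log2 change of 0.25 (camera adjusted p = 1.8e-16, and 0.70 with an estimated correlation). RPS6 rose from 1774 ± 75.2 to 2145 ± 65.4 CPM (0.27) and RPL34 from 276 ± 44.7 to 355 ± 5.01 CPM (0.36). Their pseudogene copies are numerous, 13 for RPS6, so single members are less certain than the list. Some noncoding RNAs that host small nucleolar RNAs in their introns rose as well. ZFAS1 went from 189 ± 9.44 to 287 ± 25.9 CPM (0.60, adjusted p = 4.9e-05), SNHG8 from 127 ± 27.7 to 196 ± 8.28 CPM (0.63), and GAS5 and SNHG1 rose by 0.46 and 0.34. The list of nuclear and small noncoding RNAs was fixed beforehand as a sign of RNA quality or capture. It had 6 of 15 members higher and 0 lower, or 9 higher adjusted over the list alone (median 0.33, camera adjusted p = 2.8e-06, and 0.70 with an estimated correlation). Nuclear-encoded subunits of oxidative phosphorylation had 19 higher and 1 lower of 61 tested, out of 76 in the fixed list, or 22 and 1 adjusted over the list alone (median 0.19, camera adjusted p = 7.6e-07, and 0.86 with an estimated correlation). NDUFA5 (0.55) and NDUFA12 (0.47) of complex I, UQCRB (0.42) of complex III and cytochrome c (CYCS, 0.36) were higher. After correction the medians were 0.22, 0.27 and 0.14, with 32, 5 and 9 members higher and 0 lower in each list (camera adjusted p = 5.4e-43, 9.9e-08 and 4.7e-09, and 0.53, 0.41 and 0.63 with an estimated correlation). Without control replicate 1 the corrected oxidative phosphorylation list did not pass (0.0544, median 0.08). The 2 controls differed in this respect, with ribosomal proteins at 68978 and 78170 CPM in sum, against 82244 and 83613 CPM with creatine. Without control replicate 1 the ribosomal median was 0.12 and that of oxidative phosphorylation 0.06, which did not pass (camera adjusted p = 0.107). Without control replicate 2 these medians were 0.38 and 0.33, and RPS6 did not pass without creatine replicate 2 (adjusted p = 0.0542). In the corrected fit SNHG8 (0.35), GAS5 (0.31), SNHG1 (0.22), ZFAS1 (0.63) and CYCS (0.21, adjusted p = 0.0495) passed, and RPS6 (0.14), RPL34 (0.20), NDUFA5 (0.26), NDUFA12 (0.22) and UQCRB (0.17) did not.

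Some genes of DNA replication and of cholesterol synthesis fell. CDT1, which licenses replication origins, went from 44.0 ± 2.24 to 26.8 ± 2.95 CPM (-0.72, adjusted p = 1.5e-04), and the helicase genes MCM2 and MCM5 fell by 0.47 and 0.41 on the log2 scale. Of 30 S phase genes, 15 were lower and 0 higher, or 18 lower adjusted over the list alone (median -0.24, camera adjusted p = 5.7e-08, and 0.70 with an estimated correlation). Among 32 genes of G2 and M phase, 10 were lower, among them the kinesin KIF20A (-0.54), AURKA (-0.36) and CDC20 (-0.33), and 5 were higher, or 11 and 7 adjusted over the list alone (camera adjusted p = 0.27). In the cholesterol pathway SQLE, which carries out its first oxygenation, fell from 136 ± 12.5 to 104 ± 2.10 CPM (-0.39, adjusted p = 0.0013). MVK and LSS fell by 0.54 and 0.36. The cholesterol list had 10 of 25 lower and 0 higher, or 14 and 1 adjusted over the list alone (median -0.23, camera adjusted p = 4.0e-05, and 0.70 with an estimated correlation). After correction S phase (median -0.24, camera adjusted p = 9.2e-19) and cholesterol synthesis (-0.20, 1.0e-11) passed, and the G2 and M phase list did as well (-0.18, 1.5e-13). With an estimated correlation none of these 3 passed after correction (adjusted p = 0.41, 0.35 and 0.35). CDT1, MCM2, KIF20A, AURKA, CDC20 and SQLE passed in the corrected fit (-0.43, -0.24, -0.51, -0.45, -0.24 and -0.55), and MCM5, MVK and LSS did not (-0.18, -0.27 and -0.11). In the corrected fits without 1 library, the 3 lists passed each time with the preset correlation, with adjusted p of at most 7.6e-09.

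Of 24 glycolysis genes, 13 were lower and 0 higher, or 14 and 2 adjusted over the list alone, with the lactate exporter SLC16A3 (-0.35), the glucose transporter SLC2A1 (-0.33) and ENO2 (-0.34) among them (median -0.20, camera adjusted p = 1.1e-04, and 0.70 with an estimated correlation). Fatty acid synthesis had 5 of 22 lower, among them FASN (-0.52), ACLY (-0.36) and SREBF1 (-0.41), and Wnt targets had 3 of 13 lower, SOX9 (-0.43), EPHB2 (-0.28) and MYC, with camera adjusted p = 0.043 for each list, and 0.70 for each with an estimated correlation. Adjusted over the list alone, fatty acid synthesis had 5 lower and 2 higher and Wnt targets 3 lower. After correction none of the 3 passed (camera adjusted p = 0.29, 0.35 and 0.29, medians -0.01, -0.07 and -0.03), the glycolysis list had 0 changed members, SLC16A3 was at 0.00, and ACLY (-0.21, adjusted p = 0.036) and SOX9 (-0.35, 0.0053) passed, while SLC2A1 (-0.12), ENO2 (-0.15), FASN (-0.18), SREBF1 (-0.09) and EPHB2 (-0.03) did not. Fatty acid synthesis did not pass without control replicate 1 (0.101), creatine replicate 1 (0.102) or creatine replicate 2 (0.0572), and Wnt targets did not pass with any 1 of the 4 libraries left out (0.107, 0.167, 0.197 and 0.130). EPHB2 and MYC did not pass without creatine replicate 1 (0.109 and 0.138). With the stricter filter the adjusted p was 0.0816 for fatty acid synthesis and 0.0898 for Wnt targets. Fatty acid synthesis also lost its call with upper quartile factors (0.0536), Wnt targets with no low-count filter (0.0750) and with the replicate block (0.0509), and both at equal depth (0.0515).

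**Figure D4:**
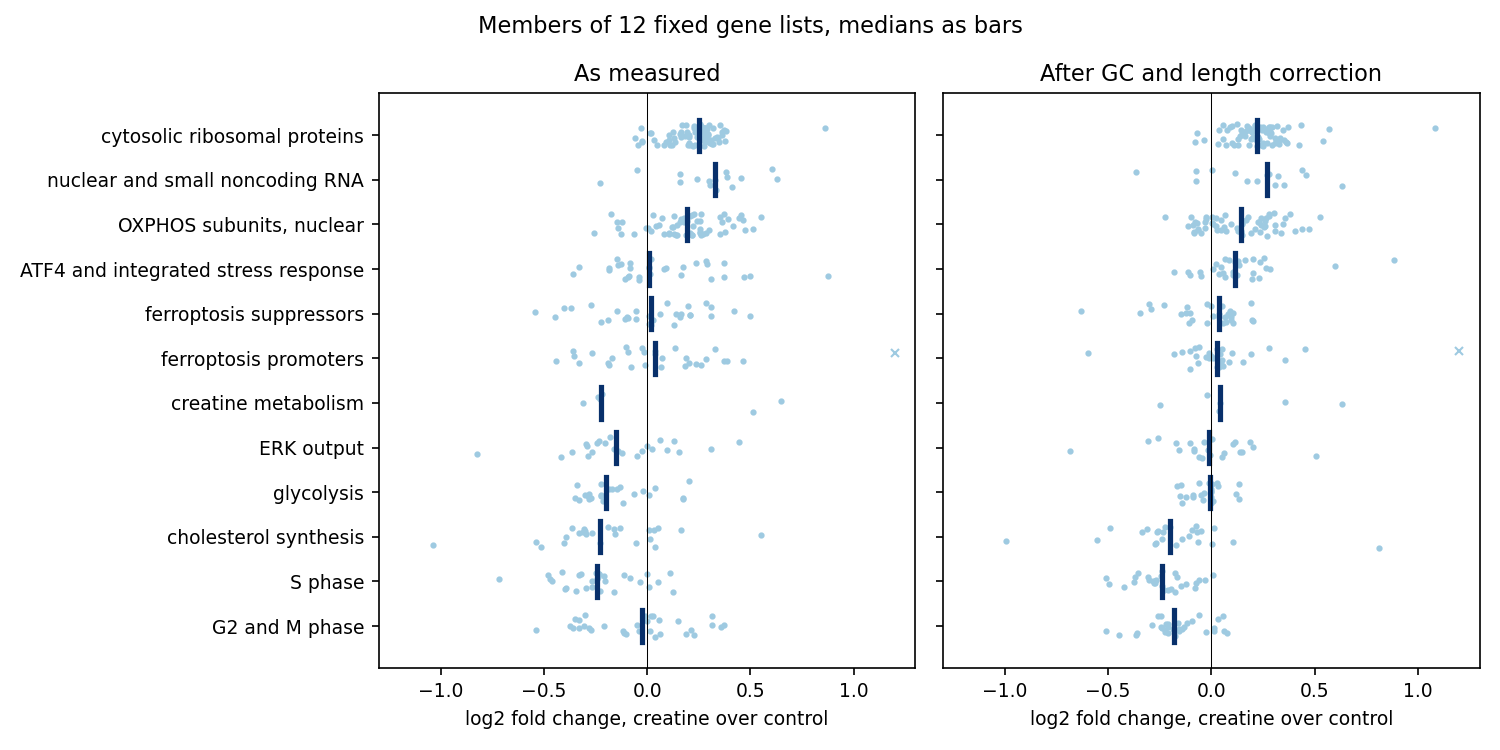
Log2 fold change, creatine over control, of the tested members of 12 gene lists (points) with the list median (bar), as measured on the left and after GC and length correction on the right, with crosses for members beyond the axis. The medians of glycolysis and ERK output move from -0.20 and -0.15 to -0.01 and -0.01, and those of ribosomal proteins and S phase from 0.25 and -0.24 to 0.22 and -0.24.

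Of 30 NRF2 targets, 2 were higher and 4 lower, among them the transketolase gene TKT (-0.33), which did not pass after correction (-0.08) (camera adjusted p = 0.78). Of 20 iron handling genes, 2 were higher and 2 lower, where the iron chaperone PCBP1 fell by 0.31 on the log2 scale and by 0.28 after correction (camera adjusted p = 0.91). Both counts were the same adjusted over the list alone. In the hypoxia list, 2 of 22 were higher and 3 lower, the same adjusted over the list alone, and the carbonic anhydrase CA9 fell from 84.6 ± 3.56 to 63.6 ± 0.511 CPM (-0.41, and -0.33 after correction), with camera adjusted p = 0.67. Antigen presentation genes had 1 higher and 3 lower of 16, the same adjusted over the list alone (camera adjusted p = 0.34), and HLA-E fell from 56.2 ± 2.03 to 37.2 ± 1.38 CPM (-0.60, and -0.41 after correction). The cytokine gene TGFB1 fell from 181 ± 4.84 to 126 ± 7.23 CPM (-0.52, and -0.29 after correction), and WFS1, of the endoplasmic reticulum stress response, fell from 27.5 ± 0.955 to 16.7 ± 0.613 CPM (-0.72, and -0.45). In all, 9 of the 38 lists passed camera, 3 higher and 6 lower, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.701. After correction 11 passed, 7 higher and 4 lower, with 5 of the 9 kept. Among those gained were p53 targets (0.034), ribosome biogenesis (0.017) and amino acid transporters (0.017), with 0.53, 0.63 and 0.77 at an estimated correlation. In corrected fits without 1 library these were lost as well, for p53 targets without control 2, creatine 1 and creatine 2 (0.209, 0.184 and 0.0800), for ribosome biogenesis without control 2 and creatine 2 (0.136 and 0.127), and for the transporters without creatine 1 (0.552). After correction the camera adjusted p was 0.60 for NRF2 targets, 0.68 for iron handling and for hypoxia, and 0.63 for antigen presentation. PCBP1 did not pass without creatine replicate 1 (adjusted p = 0.0533).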

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

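The GC and length correction, the GC correction and the equal-depth thinning were chosen after seeing the data, and the other settings were planned. Other scalings, robust estimation and limma-voom left every count of changed genes and listed members reported within 1.5 times its value, with 2964 to 3186 genes changed. Genes changed by 2-fold or more were 67 with no low-count filter and 4 with DESeq2, where the cause was not tested. Same-numbered libraries of the 2 groups did not deviate together across all tested genes (correlation -0.0228). Along GC they did, with a Spearman's rho of -0.235 for control 1 minus control 2 and -0.249 for creatine 1 minus creatine 2. Whether the numbers pair the libraries is left open. With the replicate block 3795 genes changed, 11 members of the ERK output list passed against 7, and 8 lists passed against 9, without Wnt targets (adjusted p = 0.0509).

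Leaving out 1 library leaves an arm with a single sample, assumed to vary like the other group. Changed genes then numbered 1162 to 3116, with 561 to 1378 higher, 601 to 1738 lower and 39 to 89 changed by 2-fold or more. Of the 3001 genes, 724 passed in all 4 of these fits. Lists past camera numbered 5 to 11, and members past the threshold 1 to 5 for ferroptosis suppressors, 7 to 12 for promoters, 2 to 11 for ERK output and 0 to 2 for creatine metabolism. The lowest counts of changed genes came without creatine replicate 1 (1162, 561 higher, 601 lower) and replicate 2 (1949, 739 higher). The cause was not tested. With an estimated correlation 0 of 38 lists passed, and with fry 0, against 9. Both tests of direction rest on the 2 residual degrees of freedom of the design, so few lists could pass either. Fry's test for members changed in any mix of directions uses the same fit. It passed for S phase (adjusted p = 0.011) and cholesterol synthesis (0.017), among others. It did not for ribosomal proteins (0.18), oxidative phosphorylation (0.19) or nuclear and small noncoding RNAs (0.067), among others.

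With the GC and length correction 379 genes changed, 208 higher and 171 lower, 8 by 2-fold or more, and with the GC correction 318, 186, 132 and 2. By construction both remove what follows GC content. With these 2 corrections in turn, members past the threshold were 2 and 1 for ferroptosis suppressors, 2 and 2 for promoters, 3 and 2 for ERK output and 0 and 0 for creatine metabolism. Among named genes that had passed, the sign reversed for SLC6A8 (log2 change 0.0436 with the GC and length correction, 0.0065 with the GC correction), SLC16A3 (0.00041), P4HA1 (-0.0078), CCNG1 (-0.00031), B2M (-0.0045 and -0.021) and ANKRD1 (-0.037). Among named genes that had not passed, it also differed with the GC and length correction for AIFM2 (0.04), GPX4 (0.09), MAPK3 (0.14), SPRY4 (0.11), CKB (0.04) and NCOA4 (-0.01), among others. Of the 379 genes, 80 passed in all 4 corrected fits without 1 library. At equal depth 2867 genes changed. Depth limits genes near the floor, such as GATM and DUSP6, whose changes were not detectable here.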

Other observations

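Tests on the length trend, the GC slopes and the cell identity genes, and every corrected value, were chosen after the result was seen, and the other tests in this part before theirs. For the 5' TOP and decay tests, the demand that a median clear its bound by its standard error was added after the values were seen.

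After the correction for GC content and length, targets of ATF4, the transcription factor of the integrated stress response, had 6 of 31 tested members (of 41 in the fixed list) higher and 0 lower, with a median of 0.11 (camera adjusted p = 3.2e-07, and 0.35 with an estimated correlation), against 7 higher and 2 lower before (0.36). NUPR1, a stress-induced chromatin protein gene, rose from 34.0 ± 3.32 to 47.1 ± 3.24 CPM (corrected log2 change 0.60, adjusted p = 0.0021). The list of ATF4 targets passed, with the preset correlation, in each corrected fit without 1 library, at 2.9e-07 to 3.2e-05. In the heat shock list the chaperone gene HSPA8 (-0.40), its cochaperone BAG3 (-0.45) and DNAJB1 (-0.26) were lower of 19 and 0 were higher, against 3 lower and 4 higher as measured (median 0.01, camera adjusted p = 0.90). That list passed in the corrected fit (0.042, and 0.53 with an estimated correlation) and in none of the corrected fits without control 1, control 2, creatine 1 or creatine 2 (0.0575, 0.0849, 0.262 and 0.0792). After correction the unfolded protein response, NRF2 and hypoxia lists did not pass (0.68, 0.60 and 0.68). GADD45A, a target of p53, was higher by 0.34 (adjusted p = 0.0015), as was the glutamine transporter SLC38A1 by 0.30 (0.011).

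The first pattern is that GC-rich genes fell and GC-poor genes rose with creatine. A difference in depth is argued against, since control 2 lay between the creatine libraries in depth but apart from them in GC slope. It had 49207427 counts, against 51073738 and 48249693 with creatine, and a slope of 0.13, against -0.13 and -0.08. The correlation with GC was -0.54 after thinning to equal totals, but thinning keeps each gene's expected share and so could hardly change it. The correlation with the deposited gene length was -0.0547. It was taken without regard to GC, so it cannot exclude a trend along length among genes of like GC. The median of the mitochondrial ribosome list was 0.12 with the GC correction (camera adjusted p = 2.8e-04). With length added to the correction it was 0.05 (0.24). The deposited length is 1 value per gene and not the length of the transcripts, so a difference in RNA integrity is not settled by it. The gap in GC slope between the groups was 4.61 times the largest gap within a group. Libraries of the same group also differed along GC (rho -0.235 for control 1 minus control 2, -0.249 for creatine 1 minus creatine 2). Library preparation or sequencing that differed between groups and an effect of creatine on GC-related mRNA classes cannot be told apart. The labels give no batch that crosses the groups. Simulated libraries with these trends and no changed gene gave 1800 calls, so much of the 3001 may follow the trend, and with it the lower SLC6A8, ERK output and glycolysis levels.

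The second pattern is the identity of the cells. The libraries labelled DLD-1 hold no more than 0.0334 CPM of EPCAM in any library, which is consistent with cells of another line or tissue than the label gives. The tables argue against gene symbols shifted in the table, since 5 of 5 ubiquitous genes (EEF1A1, GAPDH, EEF2, RPLP0 and ACTB) were among the 50 highest, and against a minority of other cells in an epithelial culture, since the median of EPCAM, CDH1 and KRT19 reached no more than 0.244 CPM in any library. A DLD-1 subline that lost its epithelial program stays open, and no reference profile of DLD-1 was used here. The hypothesis bears on all 4 libraries alike, and so on which cells the creatine comparison describes rather than on its direction.

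The third pattern is the rise of ribosomal protein genes and of RNAs that host small nucleolar RNAs. Of 15 host RNAs tested, 6 were higher and 0 lower after correction, with a median of 0.32. Their camera p with an estimated correlation was 0.080 as measured and 0.051 corrected. The host RNA list was not among those fixed beforehand. It holds ZFAS1, SNHG8, GAS5 and SNHG1, whose rise is given above, so its values restate that rise and add no separate evidence. For the ribosomal protein genes, a trend along GC and the deposited gene length is argued against as the whole cause. Their median of 0.25 lay at percentile 100 of 10000 lists matched on GC, that length and expression (95% of them between -0.03 and 0.05). Those lists hold unrelated genes, so the percentile does not measure how far ribosomal protein genes move together. The controls alone stood at 68978 and 78170 CPM in sum, and an effect along mRNA length was not tested. Reads moving from counted pseudogenes are argued against. The 925 pseudogenes held 336 and 426 CPM in controls and 453 and 405 CPM with creatine, too few to supply the rise. Genes and pseudogenes together rose by 0.17 (log2 of summed CPM), with both creatine libraries above both controls. Reads dropped for matching several places are in neither sum, so their part was not tested. A rise shared with other mRNAs that carry a 5' TOP element stays open. The 19 tested had a corrected median of 0.0286, with 2 higher and 0 lower (camera adjusted p = 0.045, and p = 0.14 with an estimated correlation). The median is under the bound of 0.05 set beforehand, which alone would have argued against a shared rise. It lies under that bound by less than its standard error of 0.0314, so the demand added later decides that the question stays open. The 7 factors of nonsense-mediated decay, which rise when that decay is lowered, had a corrected median of 0.0097 and none above 0.10. As measured, 2 of them were higher and 2 lower. These values argue only against a loss of decay large enough to raise the factors, and decay itself was not measured. A difference in RNA quality or capture between the control and creatine libraries was not tested and stays open. An effect of creatine on both groups of RNAs is left as a hypothesis, and its size rests on the controls. Without control replicate 1 the ribosomal median was 0.12. With an estimated correlation the ribosomal list did not pass (camera adjusted p = 0.70), in a test that 2 residual degrees of freedom leave with little power.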
